A study of Mus musculus with 12 samples.

How the data were processed

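RNA from the colon of mice of 4 genotypes was hybridised to Affymetrix whole-transcript arrays, 12 in all and 3 per genotype. Per the labels' protocols, total RNA was extracted with QIAGEN RNeasy kits and 300 ng per array were labelled with the WT PLUS kit. The values are log2 signals per probe set in 1 table of the authors, made with Affymetrix Expression Console 1.3.1.187 per the submitters' processing notes. The methods of background correction, summary and normalization between arrays and the array's genome build are not given in the sources used here. That the values are on the log2 scale rests on their range and on similar medians in all columns, since no header states it. The table holds 41345 probe sets in 12 columns, 1 per array, with no column from outside the series. It carries no detection calls, so no dim signal can be called absent, and the number of arrays limits the precision.

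Groups were taken from the genotype in the labels. Replicates were numbered in the order of the samples, so a number only names a sample and pairs nothing. Dates in the labels were not used as batches, because they run on by 1 year from sample to sample as a filled series would, and no other batch was given in the sources used here.

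Probe sets were named from the platform annotation, which lists 25335 of them. Exactly 1 symbol stood beside 23521, several beside 1814, and 16010 had none and are unnamed here. Symbols were looked up by Entrez identifier in a mouse gene table (assembly GRCm38.p6), in which 23328 matched and no symbol was updated. That table was used only for names and for the order of genes along chromosomes, and 22139 tested genes had a position. Each gene was represented by its brightest probe set over all arrays, which concerns 1082 genes with over 1 probe set and gives 22180 genes. Among the genes taken by the naming rule below, none had called probe sets of opposite sign, and other genes were not checked. No filter on dim genes was applied.

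The values were used as deposited, without further normalization. All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean per genotype and 8 residual degrees of freedom. Its empirical Bayes step added 5.56 prior degrees of freedom. The comparisons were IL10KO against WT, DKO against IL10KO, DKO against WT, SKO against WT and DKO against SKO, and the difference of the IL-10 effect between STING genotypes, (DKO minus SKO) minus (IL10KO minus WT). A gene was called where limma's moderated test gave a Benjamini-Hochberg adjusted p under 0.05. Standard errors are those of the moderated fit, and tests were 2-sided.

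Gene lists for tissue compartments, cell types and pathways were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Of 34 lists, 32 with at least 5 measured genes were tested, and 580 of 641 entries matched. Sex-linked genes (4 measured) and erythroid markers (1 measured) were not tested. Calls were set beside camera with an estimated correlation and beside fry, a self-contained test of a net shift. Members were also adjusted over the list alone. Genotype groups, tests, lists, alternatives and the naming rule were fixed before the data were examined. The naming rule takes, for IL10KO against WT and DKO against IL10KO, the 10 largest rises and 10 largest falls among called genes whose 3 arrays of one genotype all lie beyond the 3 of the other. For the other comparisons it takes 5 and 5, without the condition on arrays for the difference of effects, and for a comparison with fewer than 5 nameable calls the 5 smallest p. It adds up to 4 members with the largest difference per called list, and leaves out predicted, clone, receptor-segment and small RNA symbols. Among list members, those whose call survived every single omission were preferred as examples in the text. Lists of pancreatic acinar enzymes (15 measured) and stratified squamous and sebaceous genes (19 measured) were added after the values were seen, as was a list of pancreatic genes other than enzymes (11 measured), drawn up without looking at its own values.

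The steps were tested on simulated data. For IL10KO against WT, with 200 of 22180 genes changed, 67% of 100 genes changed by log2 1 and 96% of 100 changed by log2 2 were recovered, with 11 false calls. SKO against WT, simulated without change, gave 0 calls. For comparisons that share arrays, 100 simulations without any effect gave the value of overlap and correlation. Among the 100 genes nearest each targeted locus, calls were compared with those of other genes by Fisher's exact test.

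Alternatives were quantile normalization, median centring, leaving out the dimmest 33.3% of genes, the mean of a gene's probe sets, all probe sets, only the genotypes compared, a trended and robust variance prior, array weights, a 2-fold threshold, an estimated correlation, fry, 40 nearest genes, and leaving out each array in turn. The robust prior and the array weights used statmod 1.5.0, and the REML estimate of the weights stopped before convergence. Leaving out 3 libraries together was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.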

Results

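Gene expression was measured in the colon of mice with Affymetrix whole-transcript arrays, 1 array per sample and 12 in all. The samples fall into 4 genotypes of 3 arrays each: wild type (WT), mice lacking interleukin-10 (IL10KO), mice lacking STING (SKO) and mice lacking both (DKO). Interleukin-10 is a cytokine that restrains inflammation, and mice without it are a widely used model of spontaneous colitis. STING, encoded by Sting1 (formerly Tmem173), is a membrane adaptor that passes on the detection of DNA in the cytosol and switches on type I interferon and inflammatory genes. The design text names the comparison of the colon of the IL10KO and the double knockout, and the other genotypes serve to separate the effect of each gene. Any other difference between the groups, such as in line, tissue sampled or hour of collection, cannot be told apart from genotype. Values are log2 signals, with array medians between 4.80 and 5.02. An array has no read depth, so the number of arrays limits the precision. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples. Differences are given on the log2 scale with their standard error (SE), and group levels with their standard deviation (SD).

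The targeted genes were examined first. Sting1 (probe set 17353663) had a signal of 7.43 ± 0.62 (SD, n = 3) in IL10KO, 4.34 ± 0.06 in SKO and 4.23 ± 0.11 in DKO. In the 3 libraries labelled WT its signal was 7.51, 6.40 and 4.56, the last in the library labelled WT replicate 3, close to the knockout range of 4.13 to 4.40. Sting1 was lower in DKO than in IL10KO, with a difference of -3.20 ± 0.52 (limma adjusted p = 0.00344). Between SKO and WT the difference of -1.82 did not pass (limma adjusted p = 1), and without the library labelled WT replicate 3 it was -2.62 (limma adjusted p = 0.00263). Every comparison with WT below includes that library. Il10 (probe set 17216990) had a dim signal in WT (3.68 ± 0.11, SD, n = 3) and SKO (3.72 ± 0.09). It was higher in IL10KO (4.98 ± 0.45), by 1.29 ± 0.19 (limma adjusted p = 0.00139), and stood at 4.47 ± 0.13 in DKO. Whether this probe set lies in the deleted part of Il10 is not given in the sources used here, so its signal does not check the labels.

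**Figure D1:**
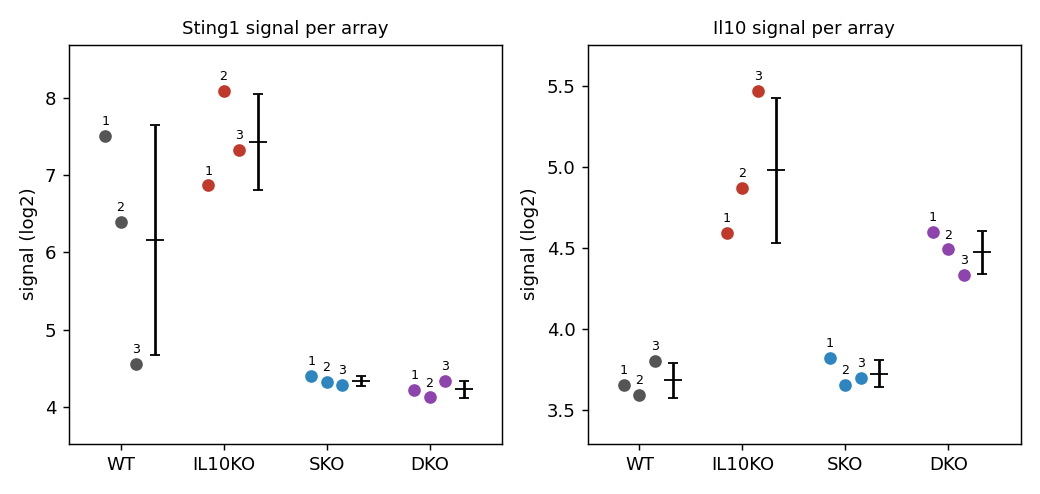
Sting1 (left) and Il10 (right) log2 signal on each array by genotype, with points numbered by replicate and bars giving the mean ± SD of 3 arrays. Sting1 lies at 4.56 in the library labelled WT replicate 3, against 7.51 and 6.40 in the other two, and between 4.13 and 4.40 in all 6 STING-knockout arrays.

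Some arrays had high signals of genes known from other tissues. Across 15 pancreatic acinar enzymes the mean signal was 8.25 in WT replicate 1 and 11.03 in WT replicate 2, and it lay between 4.34 and 4.75 in the other 10 arrays. Across 19 genes of stratified squamous epithelium and sebaceous glands the mean signal was 6.88 in IL10KO replicate 2, 7.04 in IL10KO replicate 3 and 4.93 in DKO replicate 3, with IL10KO replicate 1 just above the last. The other 8 arrays lay between 4.06 and 4.39. Both lists were drawn up after the values had been seen. Over all genes, the library labelled WT replicate 3 correlated most closely with SKO replicate 1 (r = 0.9927), the highest of the 66 pairs of arrays. The Y-linked gene Kdm5d read between 5.69 and 6.86 and Xist, the RNA that silences an X chromosome in females, between 2.49 and 3.31 in all 12 arrays. IL10KO replicate 1 stood apart most, with a median absolute deviation from the gene medians of 0.294 and a mean correlation with the other arrays of 0.957, the lowest of all. SKO replicate 2 stood apart in its genotype, with 0.181 and 0.968.

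**Figure D2:**
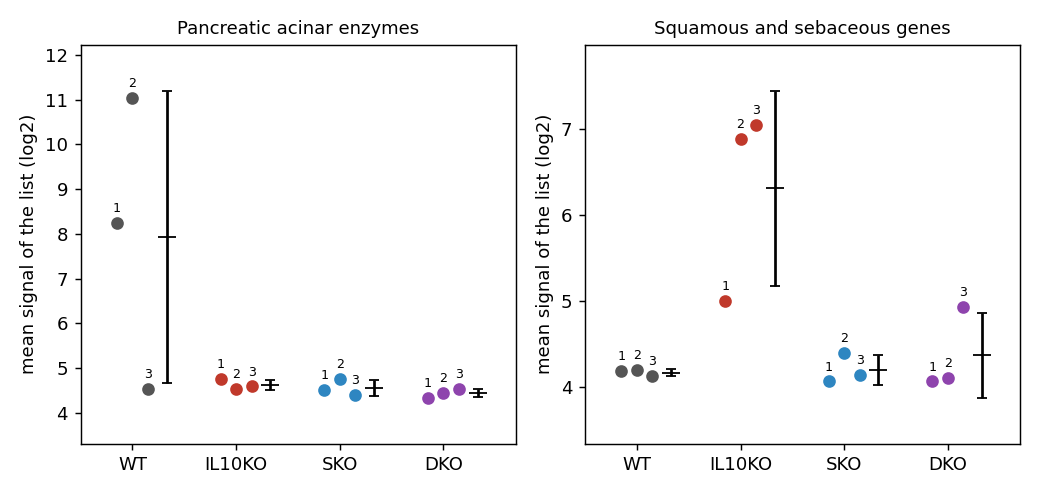
Mean log2 signal of 15 pancreatic acinar enzymes (left) and of 19 stratified squamous and sebaceous genes (right) on each array by genotype, with points numbered by replicate and bars giving the mean ± SD of 3 arrays. Acinar enzymes stand at 8.25 and 11.03 in WT replicates 1 and 2, and squamous and sebaceous genes at 6.88 and 7.04 in IL10KO replicates 2 and 3.

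The comparison of IL10KO with WT gives the change with loss of IL-10 where STING is present. The largest rise was that of Reg3g. Reg3g, a bactericidal lectin of the gut epithelium, went from 2.81 ± 0.24 (SD, n = 3) in WT to 9.37 ± 0.74 in IL10KO, a difference of 6.56 ± 0.28 (limma adjusted p = 2.33e-08). Its level in WT, like that of S100a8 (2.55), lay below the lower quartile of every array (3.45 to 3.72), so differences from such levels are read as lower bounds. Saa3, a serum amyloid A protein, rose by 6.39 ± 0.19 (limma adjusted p = 3.4e-10) and the lectin Reg3b by 6.28 ± 0.63. S100a8, a subunit of calprotectin, rose by 4.41 ± 0.44, haptoglobin (Hp) by 4.38 ± 0.35, the collagenase Mmp13 by 3.88 ± 0.35 and the neutrophil gene Retnlg by 3.83 ± 0.50. The 10 largest rises also held Clca4b (4.85), the fatty acid elongase Elovl3 (4.52) and Krt4 (3.77), a keratin of stratified epithelium. Elovl3 and Krt4 belong to the squamous and sebaceous list, of which 14 of 19 measured genes rose, with a median of 2.52. Without the library labelled WT replicate 3, 8 of them passed, with a median of 2.46.

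The 10 largest falls in IL10KO included Ang4 and 4 genes known from the exocrine pancreas. Ang4, an antimicrobial ribonuclease, was 10.78 ± 0.41 (SD, n = 3) in WT and 5.96 ± 1.60 in IL10KO, a difference of -4.82 ± 0.57 (limma adjusted p = 0.000332). Klk1b22 (-3.35), Mptx1 (-2.87), the cytochrome P450 gene Cyp2c55 (-2.83), the iron hormone gene Hamp (-2.62) and the gasdermin gene Gsdmc2 (-2.59) fell as well. The pancreatic genes were Pnliprp1 (-5.11 ± 1.06), Cpb1 (-5.01 ± 1.37), Pnliprp2 (-4.58 ± 0.85) and Clps (-4.53 ± 0.47). Their levels in WT go with WT replicates 1 and 2, which have high acinar enzyme signals. The call of Cpb1 (limma adjusted p = 0.0391) ended without any single library other than the library labelled WT replicate 3 or SKO replicate 2, reaching 0.129. That of Hamp ended without WT replicate 1, the library labelled WT replicate 3 or IL10KO replicate 1, reaching 0.107.

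Gene lists showed the same division between IL10KO and WT. Of 17 measured neutrophil markers 12 rose and none fell, with 14 higher when adjusted over the list alone and a median of 1.91 (camera adjusted p = 4.26e-14, but adjusted p = 0.0618 with an estimated correlation). S100a9 and Stfa2l1 each rose by 3.11. Of 22 epithelial defence genes 11 rose and 2 fell, Ang4 and Reg4, with 12 higher and 3 lower when adjusted over the list alone and a median of 0.86 (camera adjusted p = 3.85e-07). This was the only list of the comparison whose call held with an estimated correlation (adjusted p = 0.0103). Inflammatory cytokines rose in 8 of 22 cases, with 11 higher and 1 lower when adjusted over the list alone (camera adjusted p = 3.85e-07, and adjusted p = 0.0618 with an estimated correlation). Among them Il1b rose by 3.46 ± 0.44, Il11 by 1.96, Il1a by 1.88 and Il6 by 1.39. Of 21 chemokines 8 rose, 10 when adjusted over the list alone, led by the neutrophil attractant Cxcl5 (2.77) and including Cxcl3 (2.04) (camera adjusted p = 4.28e-06, and adjusted p = 0.181 with an estimated correlation). Of 22 macrophage and monocyte markers 7 rose, 8 when adjusted over the list alone, with Chil3 at 3.12, Arg1 at 2.38 and the Fc receptor Fcgr1 at 1.11 (camera adjusted p = 5.17e-07, and adjusted p = 0.242 with an estimated correlation). With WT replicate 2 left out, 4 chemokines and 4 macrophage markers rose, and 4 of the latter also without IL10KO replicate 3. With the library labelled WT replicate 3 left out, 6 chemokines rose and 1 fell.

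Among stromal and lymphoid lists in IL10KO against WT, 9 of 23 fibroblast and extracellular matrix genes rose and 1 fell, with 9 higher and 3 lower when adjusted over the list alone. The matrix metalloproteinases Mmp13 (3.88), Mmp10 (3.44) and Mmp3 (2.74) and the collagen cross-linking enzyme Lox (2.02) rose most (camera adjusted p = 0.000541, and adjusted p = 0.242 with an estimated correlation). Of 19 endothelial markers 3 rose, 6 when adjusted over the list alone, among them the adhesion molecules Selp (2.23) and Vcam1 (1.07) (camera adjusted p = 0.00921, and adjusted p = 0.52 with an estimated correlation). Their list call ended without IL10KO replicate 2 (camera adjusted p = 0.145). Of 13 regulatory and helper T cell genes 4 rose, 6 when adjusted over the list alone, with the costimulatory receptor gene Tnfrsf9 at 1.09 (camera adjusted p = 0.000125, and adjusted p = 0.181 with an estimated correlation). Only 1 of them rose without the library labelled WT replicate 3 or IL10KO replicate 3, and 2 without WT replicate 2. Of 20 T and natural killer cell markers 3 rose, 7 when adjusted over the list alone, and 17 did not pass (median 0.36, camera adjusted p = 0.000492, and adjusted p = 0.469 with an estimated correlation). That count was 1 without the library labelled WT replicate 3, with a median of 0.21, and 0 without any 1 of WT replicate 2, IL10KO replicate 3, SKO replicates 1 and 3 and DKO replicates 2 and 3. It was 5 without WT replicate 1 or IL10KO replicate 2, with medians of 0.66 and 0.55. None of 15 interferon-gamma-induced GTPases and related genes passed on its own or when adjusted over the list alone (median 0.48, camera adjusted p = 0.0208, and adjusted p = 0.66 with an estimated correlation). The median signal of that list was 7.50 in WT replicate 1, 5.91 in WT replicate 2 and 5.61 in the library labelled WT replicate 3, against 6.94 to 7.13 in IL10KO. With WT replicate 1 left out, 8 of the 15 rose, among them Iigp1, Ido1, Igtp and Irgm2, and the median was 0.83 (camera adjusted p = 4.93e-10). The list call ended without WT replicate 2 (median 0.34, camera adjusted p = 0.151) or the library labelled WT replicate 3 (0.28, 0.422).

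Of 17 smooth muscle markers 13 fell in IL10KO against WT and none rose, with 15 lower when adjusted over the list alone and a median of -0.76 (camera adjusted p = 4.26e-14, but adjusted p = 0.0804 with an estimated correlation). Pcp4 (-1.35), Synpo2 (-1.19) and the potassium channel subunit Kcnmb1 (-1.05) were among them. Of 18 enteric neuron and glia markers 5 fell, 8 when adjusted over the list alone, including the synaptic genes Snap25 (-1.37) and Syt1 (-1.04) (camera adjusted p = 2.02e-05, and adjusted p = 0.125 with an estimated correlation). Of 18 goblet cell markers 5 fell, 7 when adjusted over the list alone, including the mucus proteins Clca1 (-1.47) and Fcgbp (-1.25) (camera adjusted p = 2e-05, and adjusted p = 0.342 with an estimated correlation). Of 24 colonocyte markers 9 fell and 1 rose, with 13 lower and 3 higher when adjusted over the list alone. The carbonic anhydrase Car1 fell by 1.62 and the water channel Aqp8 fell by 1.26 (median -0.46, camera adjusted p = 0.000485, and adjusted p = 0.342 with an estimated correlation). Their median was -0.28 without IL10KO replicate 3, where 3 of them rose. Of 22 xenobiotic and steroid metabolism genes 9 fell, with 12 lower and 3 higher when adjusted over the list alone, among them the drug efflux pump Abcb1a (-1.43) and Gstm3 (-1.37) (camera adjusted p = 3.13e-05, and adjusted p = 0.125 with an estimated correlation). Of 18 fatty acid oxidation genes 3 fell, 5 when adjusted over the list alone (camera adjusted p = 0.0333, and adjusted p = 0.52 with an estimated correlation). The count was 1 without the library labelled WT replicate 3, 5 without IL10KO replicate 2 and none without WT replicate 1 or 2 or IL10KO replicate 1 or 3. The list call ended without WT replicate 1, IL10KO replicate 3 or SKO replicate 2 (camera adjusted p = 0.0733, 0.103 and 0.0581). Interferon-stimulated genes had a median of -0.15 and 1 of 30 fell, with none passing when adjusted over the list alone (camera adjusted p = 0.127). The list was called lower without WT replicate 2 (median -0.22, camera adjusted p = 0.0464) or the library labelled WT replicate 3 (-0.46, 0.00146), and its median was 0.12 without WT replicate 1 (0.563).

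The other 15 lists were not called in IL10KO against WT. MHC class I genes (median 0.31) and dendritic cell markers (0.27) each had a camera adjusted p of 0.0734, and no member of either passed. MHC class II genes (0.22, camera adjusted p = 0.636), proliferation genes (0.06, 0.498) and oxidative phosphorylation genes (-0.06, 0.636) had no called member either. B and plasma cell markers had 3 of 19 risen (0.12, camera adjusted p = 0.133) and distal hindgut markers 1 of 7 fallen (-0.23, 0.111). Stem and progenitor markers had 1 of 15 fallen (-0.13, camera adjusted p = 0.123) and cytosolic nucleic acid sensing genes 1 of 16 (-0.13, 0.37). Enteroendocrine and tuft cell markers had 2 risen and 3 fallen of 19 (-0.16, camera adjusted p = 0.384), mast cell and eosinophil markers 1 and 1 of 14 (-0.17, 0.384), and immediate-early and heat shock genes 2 and 3 of 17 (-0.26, 0.889). Median and test differed in sign in 3 lists. Circadian clock genes had a median of 0.12 and a mean of -0.14 and pancreatic acinar and small intestinal markers 0.02 and -1.09, and camera pointed lower for both (adjusted p = 0.636 and 0.461). Adipocyte markers had a median of 0.11 and a mean of 0.20 where camera pointed lower (adjusted p = 0.889). Several of these values rested on single libraries. With WT replicate 1 left out, MHC class I (0.53, camera adjusted p = 4.61e-07), MHC class II (0.68, 0.000491), B cell (0.38, 0.00043) and dendritic cell markers (0.38, 0.00186) and proliferation genes (0.18, 0.0499) were called higher, with 4, 1, 3, 1 and 0 members risen. With the library labelled WT replicate 3 left out, the medians of MHC class II (-0.25), B cell (-0.13, 2 risen) and adipocyte markers (-0.15) turned negative and that of immediate-early and heat shock genes (0.07) positive. Medians in that fit were 0.11 for MHC class I, 0.03 for proliferation, 0.00 for enteroendocrine and tuft cell and -0.30 for mast cell and eosinophil markers, 3 of which fell, and the acinar and small intestinal list was called lower (-0.16, camera adjusted p = 0.00472, 5 fallen). Dendritic cell markers were also called without IL10KO replicate 1 (camera adjusted p = 0.0249), and stem and progenitor markers without IL10KO replicate 2 (-0.29, 0.0286). For clock genes camera's direction turned without IL10KO replicate 1 or 3, with medians between -0.17 and 0.28 over single omissions. Those of cytosolic nucleic acid sensing genes lay between -0.25 and -0.01.

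In all, 1805 of 22180 genes passed limma's moderated test between IL10KO and WT, 693 higher and 1112 lower, and 501 of them differed by at least 2-fold. With each array centred on its median, 451 of 1475 called genes were higher. The 3 arrays of one genotype lay beyond the 3 of the other for 30% of genes, where chance gives 10%. The count was 993 without WT replicate 1, 783 without WT replicate 2, 888 without the library labelled WT replicate 3, 3070 without IL10KO replicate 2 and 1102 without IL10KO replicate 3. Of the 888 genes, 820 were among the 1805. The excess of lower calls turned at the 2-fold threshold, with 275 higher and 226 lower, and without IL10KO replicate 1, with 634 of 1205 higher. It also turned, with 566 of 1013 higher, without the library labelled WT replicate 3, IL10KO replicate 1 and SKO replicate 2 together, an omission chosen after the data had been seen.

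**Figure D3:**
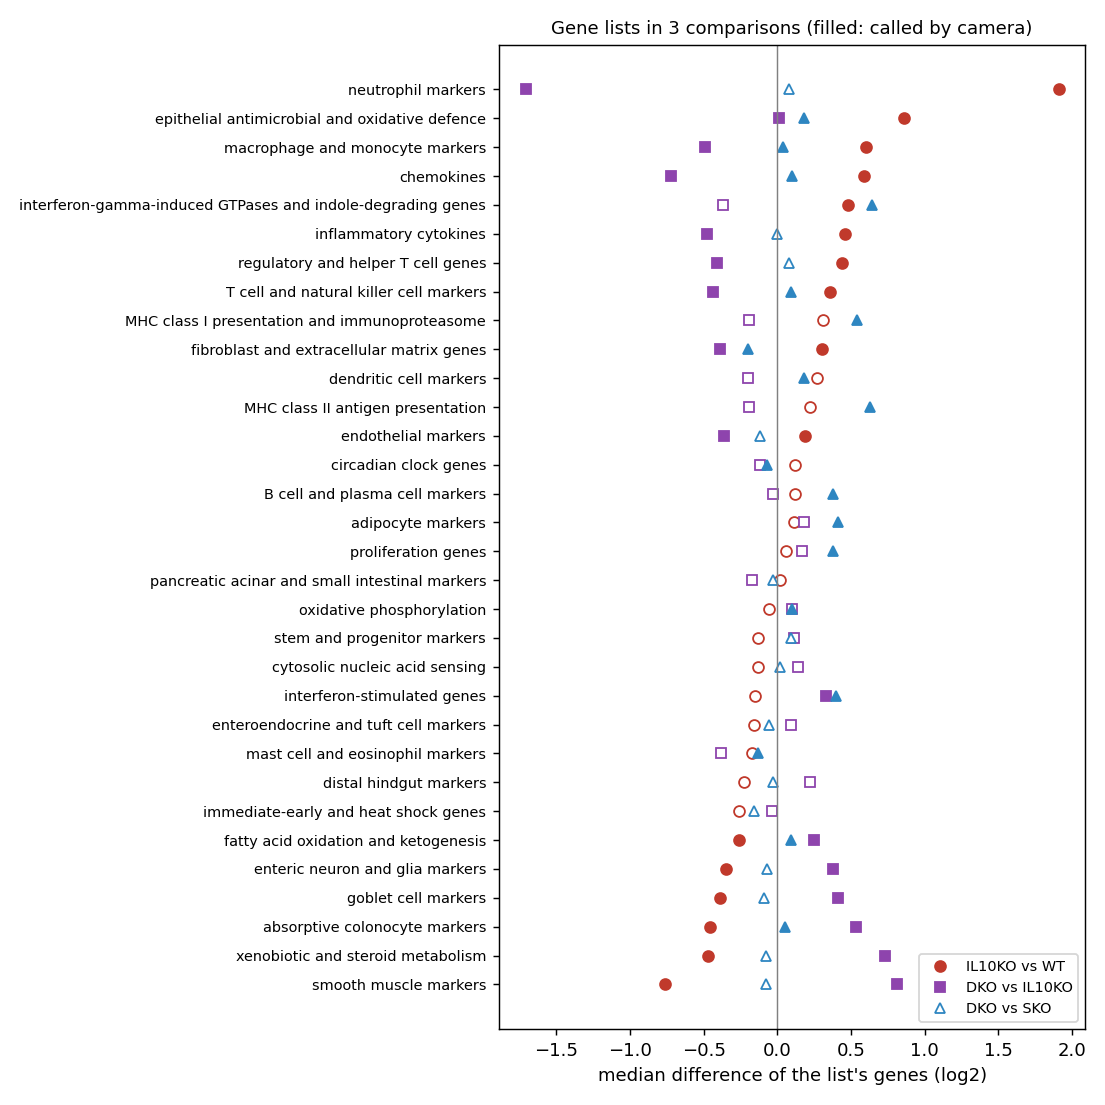
Median log2 difference of the genes of each list (horizontal axis) in IL10KO against WT (circles), DKO against IL10KO (squares) and DKO against SKO (triangles), 3 arrays per genotype, filled where camera with its preset correlation called the list. Neutrophil markers stand at 1.91, -1.71 and 0.08 and smooth muscle markers at -0.76, 0.81 and -0.08, while the medians of 7 lists, all close to 0, change sign with the scaling of the arrays in at least 1 of these comparisons.

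The comparison of DKO with IL10KO gives the change with loss of STING where IL-10 is absent. Most of the 10 genes that rose most with loss of IL-10 were among the 10 largest falls in DKO. Reg3b fell by 6.63, Reg3g fell by 6.35 and Saa3 fell by 6.31 (SE 0.63, 0.28 and 0.19). The level of Reg3g in DKO, 3.02 ± 0.19 (SD, n = 3), lay close to the 2.81 ± 0.24 of WT. Hp (-4.37), Elovl3 (-4.35), Retnlg (-4.18), S100a8 (-4.07), Mmp13 (-4.04), Mmp10 (-3.62) and the elongase Elovl4 (-3.53) completed the 10 largest falls. Of the 19 squamous and sebaceous genes, which were highest in IL10KO replicates 2 and 3, 10 fell, with a median of -2.12. The largest rises were those of Ang4 (5.43 ± 0.57, limma adjusted p = 0.000185), Klk1b22 (3.69), Mptx1 (3.06), Cyp2c55 (2.77), Retnla (2.66), Gsdmc3 (2.46), Gsdmc2 (2.35), the complement gene C7 (2.22), the steroid dehydrogenase Hsd3b3 (2.20) and the carboxypeptidase Cpm (2.11). Retnla lost its call without DKO replicate 1 or DKO replicate 3, with limma adjusted p up to 0.0748. Hsd3b3 (limma adjusted p = 0.0482) lost it without any 1 of 9 libraries, all but WT replicate 1, the library labelled WT replicate 3 and SKO replicate 2, with up to 0.138.

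Neutrophil markers fell in 12 of 17 cases in DKO against IL10KO, 13 when adjusted over the list alone, with a median of -1.71 (camera adjusted p = 3.74e-14, but adjusted p = 0.0562 with an estimated correlation). The iron-binding granule protein Ltf fell by 2.86 and S100a9 fell by 3.08. Inflammatory cytokines fell in 6 of 22 cases, with 9 lower and 1 higher when adjusted over the list alone. Il1b fell by 3.49 and Il11 fell by 1.82 (camera adjusted p = 1.64e-06, and adjusted p = 0.0562 with an estimated correlation). Of 21 chemokines 7 fell and 1 rose, with 10 lower and 1 higher when adjusted over the list alone, Cxcl5 at -2.67 and Cxcl2 at -1.65 (camera adjusted p = 2.2e-05, and adjusted p = 0.2 with an estimated correlation). Of 22 epithelial defence genes 10 fell and 1 rose, with 10 lower and 2 higher when adjusted over the list alone. Their median was 0.01, between -0.13 and 0.07 with single libraries left out, and their mean -1.32, and camera called the list lower (adjusted p = 7.72e-05, but adjusted p = 0.0546 with an estimated correlation). Of 22 macrophage markers 5 fell, 8 when adjusted over the list alone, with Chil3 at -3.13 and Arg1 at -2.03 (camera adjusted p = 2.2e-05, and adjusted p = 0.312 with an estimated correlation). Fibroblast and matrix genes fell in 6 of 23 cases and rose in 1, with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 7.42e-06, and adjusted p = 0.127 with an estimated correlation). Lox fell by 1.95 and Mmp3 fell by 2.64. Of 19 endothelial markers 4 fell, with 6 lower and 1 higher when adjusted over the list alone, Selp at -2.25 (camera adjusted p = 0.000559, and adjusted p = 0.317 with an estimated correlation). Of 13 regulatory and helper T cell genes 3 fell, 5 when adjusted over the list alone, Tnfrsf9 at -0.96 (camera adjusted p = 0.000241, and adjusted p = 0.178 with an estimated correlation). None of 20 T and natural killer cell markers passed, alone or over the list alone (median -0.44, camera adjusted p = 0.000939, and adjusted p = 0.427 with an estimated correlation). Without DKO replicate 1 the counts of fallen genes were 3 for cytokines, 3 for chemokines, 2 for endothelial markers and 1 for regulatory and helper T cell genes, and without DKO replicate 2 the last 3 were the same. Endothelial markers also stood at 2 without IL10KO replicate 1 or DKO replicate 3, regulatory and helper T cell genes at 1 without IL10KO replicate 3, chemokines at 4 and matrix genes at 10 without IL10KO replicate 2, and T and natural killer cell markers at 2 without WT replicate 1.

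Smooth muscle markers rose in 13 of 17 cases in DKO against IL10KO, 16 when adjusted over the list alone, with a median of 0.81 (camera adjusted p = 2.55e-16, but adjusted p = 0.0562 with an estimated correlation). Pcp4 rose by 1.45 and Synpo2 by 1.25. Of 24 colonocyte markers 11 rose, 13 when adjusted over the list alone, including Aqp8 (1.53), Car1 (1.44) and the transporter Abcg2 (1.41) (camera adjusted p = 8.67e-08, and adjusted p = 0.127 with an estimated correlation). Of 22 xenobiotic metabolism genes 11 rose, with 12 higher and 2 lower when adjusted over the list alone, Gstm3 at 1.36 (camera adjusted p = 1.21e-06, and adjusted p = 0.0706 with an estimated correlation). Of 18 goblet cell markers 5 rose, also 5 when adjusted over the list alone, with Clca1 at 1.41 and Fcgbp at 1.20 (camera adjusted p = 2.34e-07, and adjusted p = 0.215 with an estimated correlation). Of 18 neuron and glia markers 4 rose, 7 when adjusted over the list alone, with Snap25 at 1.34 (camera adjusted p = 7.42e-06, and adjusted p = 0.103 with an estimated correlation). Fatty acid oxidation genes rose in 1 of 18 cases, with 6 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00435, and adjusted p = 0.317 with an estimated correlation). Interferon-stimulated genes had a median of 0.33, higher in DKO, which lacks STING, with 1 of 30 risen, Oas1g (1.51), and with 4 higher and 1 lower when adjusted over the list alone. Camera called that list (adjusted p = 0.00143, and adjusted p = 0.556 with an estimated correlation). Oas1g lost its call without IL10KO replicate 1, DKO replicate 1 or DKO replicate 2 (limma adjusted p up to 0.0835), and the list call ended without DKO replicate 2 (camera adjusted p = 0.0569). No list of this comparison held its call with an estimated correlation. Without DKO replicate 1, 8 smooth muscle, 5 colonocyte, 4 xenobiotic metabolism and 3 goblet cell genes rose, and without DKO replicate 2, 5 colonocyte and 7 xenobiotic metabolism genes. The latter were also 7 without IL10KO replicate 3, and 5 fatty acid oxidation genes rose without IL10KO replicate 2. Of the other lists, proliferation genes (median 0.17, camera adjusted p = 0.0546) were called higher without any 1 of 7 libraries, mast cell and eosinophil markers (-0.38, 0.0557) and interferon-gamma-induced GTPases (-0.37, 0.0671) lower without any 1 of 3, oxidative phosphorylation (0.10, 0.0671) higher without either of 2, and stem and progenitor markers (0.11, 0.0918) higher without IL10KO replicate 2. With single libraries left out, the median lay between -0.51 and -0.22 for these GTPases and between 0.09 and 0.19 for stem and progenitor markers.

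Between DKO and IL10KO, 1284 genes passed limma's test, 740 higher and 544 lower, 380 of them by at least 2-fold. With each array centred on its median, 768 of 1110 called genes were higher. The excess of higher calls turned at the 2-fold threshold, with 164 higher and 216 lower, without IL10KO replicate 1, with 391 of 963 higher, and without DKO replicate 1, with 190 of 425. It turned as well without the library labelled WT replicate 3, IL10KO replicate 1 and SKO replicate 2 together, with 497 of 1105. The groups did not overlap for 27.2% of genes, where chance gives 10%. The count was 2361 without IL10KO replicate 2, 836 without IL10KO replicate 3, 425 without DKO replicate 1 and 504 without DKO replicate 2. Of the genes called in IL10KO against WT, 390 risen genes were lower and 617 fallen genes were higher in DKO against IL10KO, 1007 in all, and 1 was called the same way in both. Independent lists of these sizes would share 17 and 37.1, or 54.1 in all. Simulated groups with no effect that share the IL10KO arrays gave at most 1 gene called in both comparisons in any of 100 simulations. With no effect, calls are rare in either comparison, so this count is no benchmark for lists of the observed sizes. The correlation of the differences across genes, which are not independent replicates, was -0.86 against -0.50 simulated, and the covariance -0.157 against -0.0189. Each simulated gene was drawn on its own, so the simulations leave out genes that move together on an array. The 3 IL10KO arrays enter both comparisons and cannot be split into 2 sets of at least 2, so part of the excess may come from these shared arrays.

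The comparison of DKO with SKO gives the change with loss of IL-10 where STING is absent and shares no array with that of IL10KO and WT. A small set of genes differed. St3gal4, a sialyltransferase, was 9.88 ± 0.06 (SD, n = 3) in DKO and 6.38 ± 0.51 in SKO, a rise of 3.50 ± 0.29 (limma adjusted p = 9.06e-05). Nxpe4 rose by 3.43 ± 0.27, the carbonyl reductase Cbr3 by 1.74 ± 0.26 and Ceacam10 by 1.38 ± 0.21. Casp4, the inflammatory caspase that senses lipopolysaccharide, rose from 6.37 ± 0.27 in SKO to 8.38 ± 0.09 in DKO (limma adjusted p = 0.00116). Gdpd3, a lysophospholipase D, fell by 1.95 and Hddc3 fell by 1.40. In IL10KO against WT the same 7 genes were called in the same direction, St3gal4 at 3.24, Nxpe4 at 2.35 and Gdpd3 at -2.31. Reg3g stood at 2.92 ± 0.16 in SKO and 3.02 ± 0.19 in DKO.

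**Figure D4:**
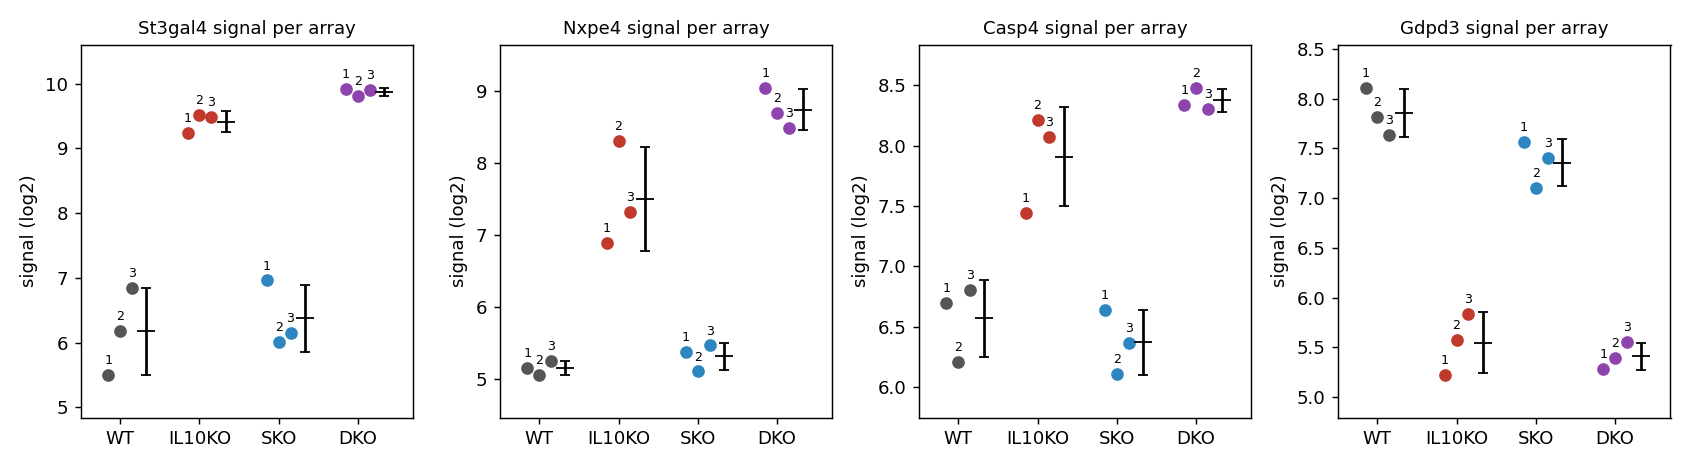
Log2 signal of St3gal4, Nxpe4, Casp4 and Gdpd3 on each array by genotype, with points numbered by replicate and bars giving the mean ± SD of 3 arrays. The IL10KO and DKO arrays lie apart from the WT and SKO arrays in each gene, with St3gal4 means of 9.41 and 9.88 against 6.18 and 6.38.

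Proliferation genes were positive in all 23 cases in DKO against SKO, with a median of 0.38. None passed over all genes, 13 were higher when adjusted over the list alone, and camera called the list (adjusted p = 5.9e-22, but adjusted p = 0.0861 with an estimated correlation). Top2a (0.76 ± 0.19) and the mitotic kinase Bub1 (0.73 ± 0.19) had the largest values. Epithelial defence genes, with a median of 0.18, 1 of 22 risen and 4 higher when adjusted over the list alone, were the only list whose call held with an estimated correlation (camera adjusted p = 3.36e-05, and adjusted p = 0.0367 with an estimated correlation). With the risen member, Ceacam10, and the other genes called in this comparison left out, that value was 0.0831. No member rose without any 1 of 8 libraries, all but WT replicate 1, the library labelled WT replicate 3 and IL10KO replicates 1 and 2. Lists tied to interferon were called higher, with no member passing, alone or over the list alone. Their medians were 0.64 for interferon-gamma-induced GTPases (camera adjusted p = 9.65e-11), 0.63 for MHC class II, 0.54 for MHC class I and 0.40 for interferon-stimulated genes, and each had adjusted p = 0.341 with an estimated correlation. The GTPase gene Iigp1 read 2.36 ± 0.69 higher and H2-Aa 1.23 ± 0.39 higher, neither past the test, though Iigp1 passed without WT replicate 1. B cell markers (0.38), dendritic cell markers (0.18) and mast cell and eosinophil markers (-0.13) were called too, and also had adjusted p = 0.341 with an estimated correlation. The fibroblast list (-0.20) had that same value, while oxidative phosphorylation (0.10) had adjusted p = 0.388 with an estimated correlation. Chemokines (0.10) had 0.442, fatty acid oxidation (0.09), colonocyte markers (0.05) and circadian clock genes (-0.07) 0.501, T cell markers (0.09) 0.508, and macrophage markers (0.04) and adipocyte markers (0.41) 0.527 as adjusted p with an estimated correlation. Of these lists, 10 lost their call with camera's preset correlation when single libraries were left out. They were mast cell and eosinophil markers without SKO replicate 1, 2 or 3 or DKO replicate 1 or 2 (camera adjusted p up to 0.0911), fatty acid oxidation without SKO replicate 1 or 2 or DKO replicate 1 (0.239), macrophage (0.205) and colonocyte markers (0.102) without SKO replicate 2 or DKO replicate 1, adipocyte markers without SKO replicate 1 or DKO replicate 1 (0.785) and clock genes without SKO replicate 1 or DKO replicate 3 (0.0793). Chemokines lost it without DKO replicate 3 (0.0569), dendritic cell markers without SKO replicate 1 (0.0509), T cell markers without SKO replicate 3 (0.0944) and oxidative phosphorylation without SKO replicate 2 (0.162). Single omissions moved several of these medians by over 1.5 times. Adipocyte markers stood at 0.02 without DKO replicate 1, 0.72 without DKO replicate 2 and 0.62 without DKO replicate 3, and B cell markers at 0.25 without DKO replicate 2. Interferon-stimulated genes stood at 0.64, macrophage markers at 0.16, colonocyte markers at 0.12, fatty acid oxidation at 0.14 and T cell markers at 0.03 without SKO replicate 3. With SKO replicate 2 left out, T cell markers stood at 0.27, chemokines at 0.23, oxidative phosphorylation at 0.04, fatty acid oxidation at 0.03 and macrophage markers at 0.01. With DKO replicate 1 left out, epithelial defence genes stood at 0.29, chemokines at 0.19, T cell markers at 0.15, fatty acid oxidation at 0.02 and clock genes at -0.15. With DKO replicate 3 left out, fatty acid oxidation stood at 0.15, dendritic cell and colonocyte markers at 0.11, macrophage markers at 0.09 and chemokines at 0.05. Mast cell and eosinophil markers stood at -0.21, colonocyte markers at 0.09 and macrophage markers at 0.08 without SKO replicate 1, and macrophage markers at 0.10 and mast cell and eosinophil markers at -0.07 without DKO replicate 2. The median adipocyte marker read 7.69 in DKO replicate 1, against 5.17 and 6.06 in the other DKO arrays and 5.22 to 5.70 in SKO. Neutrophil markers had a median of 0.08 (camera adjusted p = 0.476) and smooth muscle markers of -0.08 (camera adjusted p = 0.431), and no member of either passed.

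Between DKO and SKO, 10 genes passed limma's test, 8 higher and 2 lower, all by at least 2-fold, and the groups did not overlap for 11.1% of genes, where chance gives 10%. The count was 20 without WT replicate 1, 6 without WT replicate 2, 20 without the library labelled WT replicate 3, 5 without SKO replicate 1, 6 without SKO replicate 2, 6 without SKO replicate 3 and 5 without DKO replicate 3. Arrays of other genotypes enter because all 12 share 1 estimate of the spread. Cbr3, Ceacam10 and Hddc3 lost their calls without 7, 8 and 9 single libraries, with limma adjusted p up to 0.219, 0.242 and 0.242. Those for all 3 were SKO replicates 1 and 2, all 3 DKO replicates and WT replicate 2. Cbr3 also lost it without IL10KO replicate 2, Ceacam10 without IL10KO replicate 3 and SKO replicate 3, and Hddc3 without all of these. With array weights the count was 1940, of which 710 were higher.

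Of the 1805 genes called in IL10KO against WT, 1181 (65.4%) had the same sign in DKO against SKO, and 8 were called there as well. The 693 risen genes had a median of 0.83 in IL10KO against WT and 0.03 in DKO against SKO, with 394 of the same sign (56.9%). The 1112 fallen genes had medians of -0.74 and -0.08, with 787 of the same sign (70.8%). Camera gave p = 2.49e-05 for the risen and p = 7.29e-05 for the fallen set in DKO against SKO, and p = 0.0939 and p = 0.499 with an estimated correlation. Over all genes, which are not independent replicates, the 2 comparisons correlated with r = 0.17 and rho = 0.04. The share of the same sign lay between 53.4% without DKO replicate 3 and 75.9% without SKO replicate 2.

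**Figure D5:**
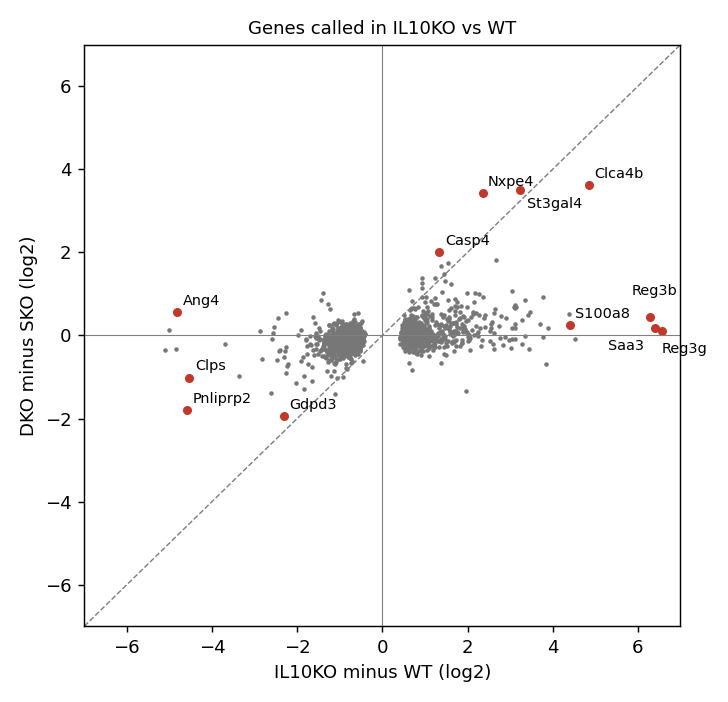
Each point is 1 of the 1805 genes called in IL10KO against WT, with its log2 difference IL10KO minus WT (horizontal axis) and DKO minus SKO (vertical axis), each from means of 3 arrays, and the dashed line marks equal differences. Reg3g lies at 6.56 and 0.10 while St3gal4 lies at 3.24 and 3.50.

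The test of the difference between the effect of IL-10 loss with and without STING, (DKO minus SKO) minus (IL10KO minus WT), asks directly whether the 2 effects part. The rise of Reg3g was smaller without STING, with a difference of -6.46 ± 0.39 (limma adjusted p = 2.69e-06), as were those of Saa3 (-6.22 ± 0.27), Reg3b (-5.82 ± 0.89), Retnlg (-4.52 ± 0.70) and S100a8 (-4.15 ± 0.62). The difference was positive for Ang4 (5.39 ± 0.81), Clps (3.51 ± 0.67), Gsdmc3 (2.74 ± 0.36), C7 (2.61 ± 0.52) and Gsdmc2 (2.50 ± 0.47). Of these, Ang4, Clps and Gsdmc2 are among the 10 largest falls of IL10KO against WT, and C7 was not called there (limma adjusted p = 0.0519). Clps in WT goes with the 2 arrays with high acinar enzyme signals. C7, Clps and Gsdmc2 lost their calls when single libraries were left out, with limma adjusted p up to 0.106, 0.0992 and 0.0691. DKO replicates 1 and 3, IL10KO replicate 3 and SKO replicate 3 did so for all 3 genes, DKO replicate 2 for Clps and Gsdmc2, SKO replicate 2 for C7 and Clps, WT replicates 1 and 2 for C7 and Gsdmc2, and SKO replicate 1 for C7.

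Of 17 neutrophil markers 5 passed the test of this difference, all negative, and 12 when adjusted over the list alone, with a median of -1.68 (camera adjusted p = 8.23e-13, but adjusted p = 0.0862 with an estimated correlation). The count was 12 without IL10KO replicate 1, 8 without IL10KO replicate 2, 3 without DKO replicate 1 and 2 without SKO replicate 2 or DKO replicate 2. Smooth muscle markers had a median of 0.71 with 2 of 17 called and 11 when adjusted over the list alone (camera adjusted p = 4.19e-12, and adjusted p = 0.117 with an estimated correlation), and single omissions left 0 to 5 called. Fibroblast and matrix genes had a median of -0.52 with 5 of 23 called, including Mmp10 (-3.77 ± 0.36) and Lox (-2.07 ± 0.26), and with 10 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.48e-06, and adjusted p = 0.126 with an estimated correlation), and single omissions left 3 to 7 lower. Of 24 colonocyte markers 2 were called, including Aqp8 (1.51 ± 0.23), and 10 when adjusted over the list alone (camera adjusted p = 4.48e-06, and adjusted p = 0.223 with an estimated correlation), and single omissions left 1 to 5. Of 22 epithelial defence genes 9 were lower and 1 higher, with 10 and 2 when adjusted over the list alone. Their median of 0.02 and mean of -1.24 differ in sign, the median is -0.13 after quantile normalization and 0.10 after median centring, and camera called the list lower (adjusted p = 5.64e-05). It alone of 18 called lists held with an estimated correlation (adjusted p = 0.0463). Its median lay between -0.47 without the library labelled WT replicate 3 and 0.13 without WT replicate 1. In the former fit 24 lists were called. The 6 added, all positive, were MHC class I (median 0.49, camera adjusted p = 0.000974), acinar and small intestinal markers (0.52, 0.000683), interferon-gamma-induced GTPases (0.57, 0.00586), cytosolic nucleic acid sensing (0.29, 0.0439), B cell markers (0.36, 0.0471) and adipocyte markers (0.74, 0.0472).

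Of all genes, 143 passed limma's test of the difference, 62 positive and 81 negative. All 143 were also called in DKO against IL10KO, and 136 were called with the opposite sign in IL10KO against WT. The tests share arrays, so this overlap is partly built in. The count was 73 without WT replicate 1, 51 without WT replicate 2, 168 without the library labelled WT replicate 3, 316 without IL10KO replicate 1, 376 without IL10KO replicate 2, 57 without SKO replicate 1, 55 without SKO replicate 2, 75 without SKO replicate 3, 59 without DKO replicate 1 and 50 without DKO replicate 2. Positive calls outnumbered negative ones without IL10KO replicate 2, with 227 of 376.

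DKO was compared with WT as the colon without either gene against that with both. St3gal4 was 9.88 ± 0.06 (SD, n = 3) in DKO against a mean of 6.18 in WT (limma adjusted p = 3.42e-05), and Nxpe4 rose by 3.59 ± 0.27, Casp4 by 1.81 ± 0.21, Ceacam10 by 1.54 ± 0.21 and the neutrophil antigen gene Cd177 by 1.52 ± 0.24, while Gdpd3 fell by 2.45. Mast cell and eosinophil markers were negative in all 14 cases, with a median of -0.37, none past the test and 1 lower when adjusted over the list alone. The mast cell protease genes Mcpt1 (-1.95 ± 0.71) and Cma1 (-0.94 ± 0.21) had large values. Camera called that list (adjusted p = 2.35e-08) and epithelial defence genes (median 0.11, 1 of 22 risen, 3 when adjusted over the list alone, adjusted p = 0.00015), and both calls held with an estimated correlation (adjusted p = 0.0291 each). No epithelial defence gene rose without WT replicate 1 or 2 or DKO replicate 1 or 2. The lists of proliferation genes (0.23), colonocyte markers (0.14), interferon-stimulated genes (0.14) and oxidative phosphorylation (0.13) were called higher with no member passing, alone or over the list alone, and had adjusted p = 0.588, 0.642, 0.839 and 0.764 with an estimated correlation. The interferon-stimulated list had, without the library labelled WT replicate 3, a median of 0.00 (camera adjusted p = 0.913), and without WT replicate 1 one of 0.43 (2.69e-14). Its call ended too without WT replicate 2 (0.137) or DKO replicate 2 (median 0.04, 0.684), and that of oxidative phosphorylation without WT replicate 2 (0.0645). The median of oxidative phosphorylation lay between 0.08 and 0.13 with single libraries left out. MHC class II was called lower without the library labelled WT replicate 3 (median -0.50, camera adjusted p = 0.000219) and higher without WT replicate 1 (0.45, 6.66e-08). The latter omission also brought calls, all higher, of interferon-gamma-induced GTPases (0.45, camera adjusted p = 2.69e-14), MHC class I (0.42, 8.83e-13), B cell (0.41, 1.08e-06), dendritic cell (0.27, 0.000416), T cell (0.20, 1.03e-06) and macrophage markers (0.16, 4.29e-05), chemokines (0.13, 9.13e-06), regulatory and helper T cell genes (0.12, 0.0107) and cytokines (0.06, 0.0284), and, lower, of fibroblast (-0.18, 0.00996) and clock genes (-0.04, 0.0222). Epithelial defence genes stood at 0.18 and mast cell and eosinophil markers at -0.24 there, the former at 0.23 without DKO replicate 1 and 0.07 without DKO replicate 2, and colonocyte markers at 0.06 without WT replicate 2 and 0.09 without DKO replicate 2. Without the library labelled WT replicate 3, goblet cell (0.20, 3.37e-05), enteroendocrine and tuft cell (0.09, 0.00242) and smooth muscle markers (0.10, 0.026) were called higher. Pancreatic acinar and small intestinal markers were called lower, with 4 lower and 1 higher when adjusted over the list alone (median -0.07, mean -1.13, and adjusted p = 0.764 with an estimated correlation), and go with the acinar enzymes in WT replicates 1 and 2. That call ended without WT replicate 1 (camera adjusted p = 0.0901), IL10KO replicate 2 (0.0537) or DKO replicate 1 (0.144), and the median was -0.22, with 5 members fallen, without the library labelled WT replicate 3, -0.20 without DKO replicate 3, -0.14 without WT replicate 2 and -0.02 without DKO replicate 1.

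Between DKO and WT, 10 genes passed limma's test, 9 higher and 1 lower, 648 had an unadjusted p under 0.05, and the groups did not overlap for 9.40% of genes, where chance gives 10%. The count was 5 without WT replicate 2, 69 without the library labelled WT replicate 3, 5 without DKO replicate 1 and 6 without DKO replicate 2. The number of called lists went from 7 to 18 without WT replicate 1 and to 13 without DKO replicate 1. Ceacam10 lost its call without WT replicate 1, WT replicate 2, DKO replicate 1 or DKO replicate 2 (limma adjusted p up to 0.133), and Cd177 without any single library but the library labelled WT replicate 3 (up to 0.315).

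SKO was compared with WT for the effect of STING loss where IL-10 is present, and no gene passed limma's test, with 454 genes at an unadjusted p under 0.05. The genes with the smallest p were Lpo (-2.74 ± 0.71), Pnliprp1 (-4.11 ± 1.06), Cpb1 (-5.12 ± 1.37), Ppp1r14c (0.75 ± 0.20) and Zan (-2.01 ± 0.56), none of which passed (limma adjusted p = 1). Pnliprp1 and Cpb1 go with the acinar enzymes in WT replicates 1 and 2. Without the library labelled WT replicate 3, 55 genes passed, 23 higher and 32 lower, 10 of the 15 acinar enzymes among the lower. The groups of 3 did not overlap for 6.21% of genes, where chance gives 10%.

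Camera called 13 lists in SKO against WT, with no member of any past the test with all 12 arrays, and none held with an estimated correlation. Lower lists were MHC class II (median -0.69), interferon-gamma-induced GTPases (-0.61), MHC class I (-0.37), B cell markers (-0.31), proliferation genes (-0.20), pancreatic acinar and small intestinal markers (-0.19) and mast cell markers (-0.18), all with adjusted p = 0.277 with an estimated correlation. Interferon-stimulated genes (-0.26), chemokines (-0.14), T cell markers (-0.12) and cytosolic nucleic acid sensing genes (-0.11) were called lower, and smooth muscle markers (0.13) and goblet cell markers (0.17) higher, all with adjusted p = 0.594 with an estimated correlation. Adjusted over the list alone, 3 acinar and small intestinal markers were lower and no member of the other 12 lists passed. H2-Aa read -1.25 ± 0.39, Iigp1 -1.81 ± 0.69 and the cell cycle gene Mki67 -0.42 ± 0.15, none past the test. The median signal of MHC class II genes was 8.43 in WT replicate 1, 7.05 in WT replicate 2 and 6.37 in the library labelled WT replicate 3, against 6.40, 6.48 and 6.67 in SKO. Without WT replicate 1, 5 lists were called, all lower, which were MHC class II (-0.22), GTPases (-0.17), acinar and small intestinal markers (-0.08), proliferation genes (-0.07) and, in addition, adipocyte markers (-0.56). The other 9 lost their call, with camera adjusted p between 0.106 and 0.886, and the medians of interferon-stimulated genes (0.01), chemokines (0.02) and T cell markers (0.07) turned positive. Calls also ended without SKO replicate 1 for chemokines, T cell and goblet cell markers (up to 0.518), without SKO replicate 2 for interferon-stimulated and nucleic acid sensing genes (up to 0.24) and without SKO replicate 3 for chemokines, T cell and smooth muscle markers (up to 0.218). Medians moved by over 1.5 times without SKO replicate 1 (interferon-stimulated genes -0.14, T cell markers -0.05, goblet cell markers 0.04), SKO replicate 2 (interferon-stimulated genes -0.10, chemokines -0.26, T cell markers -0.24, B cell markers -0.49, proliferation genes -0.12, acinar and small intestinal markers -0.39), SKO replicate 3 (interferon-stimulated genes -0.47, chemokines -0.05, T cell markers -0.07, mast cell markers -0.10, acinar and small intestinal markers -0.06) or WT replicate 2 (chemokines -0.23).

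In SKO against WT without the library labelled WT replicate 3, 17 lists were called, and several medians were larger. MHC class II stood at -1.14 with 2 of 10 members fallen, B cell markers at -0.61, T cell markers at -0.33, MHC class I at -0.56, interferon-stimulated genes at -0.47, mast cell markers at -0.31, proliferation genes at -0.30 and goblet cell markers at 0.32. In the same fit 1 of 16 cytosolic nucleic acid sensing genes and 3 of 14 acinar and small intestinal markers fell. Dendritic cell (-0.20, camera adjusted p = 0.0192) and adipocyte markers (-0.72, 0.00884) were called lower, and enteroendocrine and tuft cell markers (0.13, 0.0121) and fibroblast genes (0.15, 0.0189) higher.

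Genes next to the targeted loci were not called more often than other genes. Of the 100 nearest tested genes of Il10, 7 were called in IL10KO against WT (7%, against 8.15% of the others, Fisher's exact p = 0.854, 1 after adjustment over the tests with 100 neighbours) and none in DKO against SKO, where limma called 10 genes in all. Of those of Sting1, 2 were called in DKO against IL10KO (2%, against 5.81%, Fisher's exact p = 0.13, adjusted 0.52) and none in SKO against WT, where limma called none.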

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

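The tests on the library labelled WT replicate 3, on the acinar enzymes and on the genes that differ between DKO and SKO were chosen only after those results were seen, whereas the counts over other splits of the arrays were planned and the test on pancreatic genes other than enzymes was set before its values were seen. The test of the difference of the IL-10 effect between STING genotypes singled out 143 genes. Among the named ones the difference was -6.46 for Reg3g, -6.22 for Saa3, -5.82 for Reg3b, -4.52 for Retnlg, -4.15 for S100a8, -3.85 for Hp and -3.69 for Mmp13. It was 5.39 for Ang4, 3.51 for Clps, 2.74 for Gsdmc3, 2.61 for C7 and 2.50 for Gsdmc2.

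The same test singled out 18 gene lists by camera with its preset correlation. Lists with a negative median were neutrophil markers (-1.68), fibroblast and matrix genes (-0.52), macrophage markers (-0.47), inflammatory cytokines (-0.43), chemokines (-0.39), endothelial markers (-0.38) and regulatory and helper T cell genes (-0.37). Lists with a positive median were smooth muscle markers (0.71), interferon-stimulated genes (0.64), xenobiotic metabolism (0.63), colonocyte markers (0.51), MHC class II (0.40), proliferation genes (0.36), neuron and glia markers (0.32), fatty acid oxidation (0.31), stem and progenitor markers (0.26) and goblet cell markers (0.25). Epithelial defence genes had a median of 0.02 and a mean of -1.24, and were the only ones whose call held with an estimated correlation (adjusted p = 0.0463). The other 17 had camera adjusted p between 0.0862 and 0.618 with an estimated correlation. The median of MHC class II was 0.85 without the library labelled WT replicate 3, with 1 member called, and -0.01 without WT replicate 1, where the call ended (camera adjusted p = 0.623). It ended as well without IL10KO replicate 1 or 2, SKO replicate 1 or DKO replicate 2 or 3 (up to 0.0887), that of stem and progenitor markers without IL10KO replicate 1 or 3 or SKO replicate 2 (up to 0.0919, with a median of 0.09 without the last) and that of endothelial markers without IL10KO replicate 2 (0.0802). Other medians moved by over 1.5 times without WT replicate 1 (interferon-stimulated genes 0.40, chemokines -0.81), WT replicate 2 (macrophage markers -0.24), IL10KO replicate 2 (endothelial markers -0.23) or DKO replicate 1 (fatty acid oxidation 0.18, stem and progenitor markers 0.17).

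Probe sets with no gene name or with several lay outside the tested genes. Of 17824 such probe sets, limma called 331 in IL10KO against WT when all 41345 were tested. That is a smaller share than over all probe sets, of which 1229 were called. In DKO against IL10KO, DKO against WT, SKO against WT, DKO against SKO and the difference of effects, 226, 3, 0, 4 and 7 of the 17824 were called.

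Sting1 in the library labelled WT replicate 3 stood at 4.56, near the level of the STING knockouts. A swap with a STING-knockout library of the series is argued against, since 0 of the SKO and DKO libraries had Sting1 above 5.83, the midpoint of the IL10KO and DKO means. A poor array is argued against too, since its median absolute deviation from the gene medians was 0.0817, below the 0.0897 to 0.294 of the others. A wrong label stays open as a hypothesis: of 44 genes called between SKO and WT without this library, acinar enzymes and Sting1 left out, it lay closer to the SKO mean for 44, or 100%. The other 2 WT libraries have high acinar enzyme signals, so part of that share may reflect what sets those 2 apart, and no biological explanation was tested.

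Acinar enzymes stood out in WT replicates 1 and 2. The STING genotype alone as their source is argued against, since IL10KO carries STING and the median IL10KO minus SKO difference was 0.18. The enzymes were listed after these values were seen, so that difference restates the pattern and is no separate test. RNA of the pancreas may be the source. That both libraries lay above all 10 others for 13 of 15 enzymes restates the pattern too, since the list came from it. Of 11 pancreatic genes other than enzymes, listed before their values were looked at, both lay above all 10 others for 2, or 18.2%. This is under the 25% set beforehand as speaking against that source. The exact binomial 95% interval of 2.28 to 51.8%, computed once the result was seen, spans it. That interval takes the genes as independent, though all were read on the same 2 libraries, so it gives no spread between libraries. Pancreas as the source thus stays open for the 2 libraries together. The rule needed both to stand out, and WT replicate 1 had the lower acinar mean, 8.25 against 11.03 in WT replicate 2. It could therefore miss dimmer pancreatic genes in WT replicate 1, and Spink1 also reached 10.88 outside these 2 libraries. WT replicate 2 alone lay above all 10 others for 11 of 11, with Gp2 at 10.27 and Cuzd1 at 10.19, and WT replicate 1 for 2, a count made after the result was seen.

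The 10 genes called between DKO and SKO were set against inflammation and strain background. Inflammation with neutrophil markers, of the size seen in IL10KO, is argued against as their common cause, since the 17 markers had a median of 0.08 (SD of the markers 0.26, and 0.03 to 0.13 with single libraries left out) in DKO against SKO, far under 0.95, midway between 0 and their median of 1.91 in IL10KO against WT, where 8 of the 10 genes were called too. A milder inflammation, or one without neutrophil markers, stays open, since of 4 other inflammatory lists, the 10 genes left out, camera called 0 with an estimated correlation but chemokines, macrophage markers and epithelial defence genes higher with its preset one (adjusted p = 0.00417, 0.00804 and 0.000843). A strain or donor variant, from a different breeding background of the Il10-knockout lines, may account for them, since 9 of 10 had the same sign in IL10KO against WT. None of the 10 lay within 25 tested genes of another (share of 10000 random sets with as many neighbours = 1). That count decides nothing, since the genes are few and the window misses longer shared stretches of a chromosome. A count of 0 also gives that share for any set, and how many of the genes share a chromosome was not counted. An effect of IL-10 loss without inflammation also stays open, because every Il10-knockout array shares both the genotype and any background.

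Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For IL10KO against WT the real split gave 1805 genes and the highest other 4, with 1 split as large in all. The values were 1284 and 6 for DKO against IL10KO, 10 and 0 for DKO against WT and 10 and 0 for DKO against SKO, each with 1 split as large. SKO against WT gave 0 genes against a highest other of 4, so that 10 of 10 were as large. For the difference of effects, 100 splits within the IL-10 genotypes were counted, the real one and others drawn at random. Of these, 7 gave as many as 143 genes, the highest other 315, so chance was not excluded. The 12 splits that kept IL10KO and DKO as labelled gave 85 to 315 genes and the 88 that mixed them gave 0. That count follows the split between IL10KO and DKO more than the one between WT and SKO. Since those 12 splits keep the difference between IL10KO and DKO, the share of 7 in 100 cannot decide.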

How the results depend on the processing

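All alternatives but 1 were fixed beforehand. The omission of 3 libraries together (the library labelled WT replicate 3, IL10KO replicate 1 and SKO replicate 2, the last 2 with the lowest mean correlation of their genotypes) was chosen after seeing the data. No paired analysis was possible because the labels share no replicate numbers between groups and those used here only follow the order of the samples. No called gene that is named changed sign under these alternatives, but camera's direction turned, with no call left, in SKO against WT without WT replicate 1 for interferon-stimulated genes, chemokines and T cell markers, and in DKO against WT without the library labelled WT replicate 3 for interferon-stimulated genes. Under quantile normalization, median centring, the mean of probe sets, omission of the dimmest 33.3% of genes and a trended and robust prior, every total of called genes and of called lists stayed within 1.5 times its value, and the share of IL10KO against WT calls with the same sign in DKO against SKO lay between 64.5% and 67.5%. A 2-fold threshold, which only removes genes, left 501 genes in IL10KO against WT and 380 in DKO against IL10KO. With an estimated correlation 1, 0, 2, 0, 1 and 1 lists were called in IL10KO against WT, DKO against IL10KO, DKO against WT, SKO against WT, DKO against SKO and the difference of effects, in place of 16, 16, 7, 13, 18 and 18. Fry called 1, 0, 1 and 8 lists in the last 4. All probe sets gave 828 calls in DKO against IL10KO and 30 for the difference, with more tests to adjust for. Only the genotypes compared gave 704, 489 and 41 genes in IL10KO against WT, DKO against IL10KO and DKO against SKO. Array weights gave 33 genes in DKO against WT, 1940 in DKO against SKO, 736 for the difference and a share of 73.1%. They gave SKO replicate 1 a weight of 13.6, and their estimate had not converged. Without the 3 libraries, 1013 (566 higher), 78, 50 and 21 genes were called in IL10KO against WT, DKO against WT, SKO against WT and DKO against SKO, 1105 (497 higher) in DKO against IL10KO, 245 for the difference, and 20 lists in SKO against WT. Single omissions gave 783 to 3070 genes in IL10KO against WT, 425 to 2361 in DKO against IL10KO, 5 to 69 in DKO against WT, 0 to 55 in SKO against WT, 5 to 20 in DKO against SKO and 50 to 376 for the difference. They gave 15 to 20, 16 to 19, 7 to 18, 5 to 17, 13 to 18 and 16 to 24 lists in the same order, and shares of 53.4% to 75.9%. Where one array of a genotype was left out, 2 remained. Where no construction is named, the cause was not tested. With the 40 nearest genes, Fisher's exact p for neighbours of the targeted loci lay between 0.255 and 1. The number of arrays limits the precision, and without detection calls dim genes such as Il10 cannot be set against background.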

Other observations

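Clock genes moved in both directions. In IL10KO against WT, 2 of 15 circadian clock genes rose and 4 fell, with 3 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.636), and without the library labelled WT replicate 3, 1 rose and 2 fell. The clock activators Arntl (-1.58 ± 0.20, SE, n = 3 per genotype) and Npas2 (-1.58 ± 0.22) fell and Ciart (0.91 ± 0.15) rose. In DKO against IL10KO, 3 rose and 4 fell, with 5 higher and 6 lower when adjusted over the list alone, Arntl (1.74 ± 0.20) and Npas2 (1.67 ± 0.22) among the former and the output gene Dbp (-1.39 ± 0.18) and Nr1d1 (-1.46 ± 0.34) among the latter. Nr1d1 lost its call without IL10KO replicate 2, DKO replicate 2 or DKO replicate 3 (limma adjusted p up to 0.0829). For Arntl the DKO minus SKO difference exceeded the IL10KO minus WT difference by 1.87 (limma adjusted p = 0.011). In DKO against SKO no clock gene passed over all genes, while 1 was higher and 4 were lower when adjusted over the list alone, with Nr1d1 at -1.65 and Dbp at -0.84. Camera called the list lower there (adjusted p = 0.0141, but adjusted p = 0.501 with an estimated correlation), a call that ended without SKO replicate 1 (0.0647) or DKO replicate 3 (0.0793). The WT values include the library labelled WT replicate 3, and the hour of collection is not given in the sources used here.

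Single members of uncalled lists also differed. The enteroendocrine peptide gene Insl5 fell by 1.25 in IL10KO against WT and rose by 1.40 in DKO against IL10KO. Ier3, an early-response gene, rose by 2.05 and fell by 2.20 in these comparisons. Among plasma cell genes Mzb1 (0.94) and Prdm1 (0.82) rose in IL10KO against WT.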
